A study of Mus musculus with 17 samples.

How the data were processed

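The study measured where RUNX1, a haematopoietic transcription factor, and CHD7, a chromatin remodeller of the chromodomain helicase family, sat on DNA in 416B cells, a mouse myeloid progenitor line. Per the labels' protocols, the cells carried either a doxycycline-inducible Cbfb-Myh11 fusion cDNA (CM, the fusion found in acute myeloid leukaemia with inversion of chromosome 16) or the same vector without it. Doxycycline was given at 1 ug/ml for 24 hours where the labels say so. Chromatin was crosslinked with 1% formaldehyde, sonicated and immunoprecipitated, and libraries were size-selected for 150 to 400 bp, per the labels' protocols. The labels name 17 samples: 2 replicates of each of 4 conditions (Control -Dox, Control +Dox, CM -Dox, CM +Dox) for each antibody, and 1 IgG sample whose values were not analysed here.

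Each of the 16 libraries has its own peak list, so peaks were called per sample. Per the submitters' processing notes, the tools were Bowtie2 2.0.6 and MACS2 2.0.10 on the mm10 build; the background library of the peak calls, read filters and read depths are not given in the sources used here. The score that the authors deposited for each peak is the −log10 of its p-value. That reading was checked on the values, since the lowest score of each list lies just above the threshold written in its peak names. These deposited p-value thresholds differ between lists: 1e-09 in 5 RUNX1 lists, 1e-07 in 3 RUNX1 lists and 0.01 in all 8 CHD7 lists. The score was used only to rank or filter peaks within a list. Depth is unknown, so peak numbers and scores are not read as amounts of binding.

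The peak names of the library labelled Control -Dox RUNX1 replicate 1 carry a +Dox tag, against its label. It was kept in the group its label gives. Neither condition it could belong to contains the fusion protein. The tag is missing from some lists labelled +Dox, such as Control +Dox RUNX1 replicate 2 and CM +Dox RUNX1 replicate 2. The library with the mismatched tag is 1 of the 2 that define the baseline RUNX1 sites used below.

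Peaks on chromosomes 1 to 19, X and Y were used. Peaks of the 8 lists of an antibody were merged into sites where they overlapped by 1 bp or more, and a site counted as called in a library when a peak of that library overlapped it. Baseline RUNX1 sites were those called in both Control -Dox libraries. A lost site was called in all 6 libraries without CM and in neither CM +Dox library; a gained site was called in both CM +Dox libraries and none of the 6. CHD7 preference for RUNX1 sites was, per library, the log2 odds ratio of being called at CHD7 sites on baseline RUNX1 sites against CHD7 sites with no RUNX1 peak in any library, with 0.5 added to each count. Co-occupancy was set against the mean of 100 random shifts of each peak by 10 to 100 kb.

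Each test used 1 value per library. CM +Dox (2 libraries) was compared with the other 6 libraries of the antibody by a two-sided exact permutation test over all 28 choices, whose smallest p is 0.0357. Retention at baseline sites compared 2 with 4 libraries over 15 choices, whose smallest p is 0.0667, so it cannot reach 0.05. Comparisons of 2 with 2 libraries have a smallest p of 0.333. No p-value was given to single sites. Benjamini-Hochberg adjustment ran over the 12 tests of this kind. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Wilson 95% intervals of shares of sites cover counting error only.

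Gene positions came from the RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 denotes, with 21883 protein-coding genes and no strand or exons. Promoters could therefore not be told from gene 3' ends, and the planned promoter share was computed as the share of peaks within 1 kb of either end of a gene. Site annotations are limited to inside a gene or the distance to the nearest gene boundary; exon, intron and UTR were not used here. The planned count of RUNX motifs needs a genome sequence and was not run. Of 11 gene lists fixed before the data were examined, all 207 genes matched the table. A gene counted as bound when a site called in both replicates lay in its body or within 5 kb of either end, and each list was compared with 10000 random lists matched on 10 groups of gene length, with Benjamini-Hochberg adjustment over the 22 tests of a condition. The lists were not matched on expression.

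Genes and sites were named by a rule fixed before the data were examined: up to 10 sites each of those called in all 16 libraries, RUNX1 lost, RUNX1 gained, CHD7 lost and CHD7 gained, by mean percentile rank of their score within the lists that call them (100 the highest); up to 4 genes per list by the mean rank of their best RUNX1 peak, with 0 where a library had none; and Runx1, Chd7, Cbfb and Myh11. Other genes are named where a count of 5 or fewer is given.

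The alternatives tried were a stricter score, the same number of peaks in every list of an antibody (8140 for RUNX1, 16323 for CHD7), all sequences, an overlap of at least 0.5 of the shorter interval, baseline sites from Control +Dox, wider windows, permutation within replicate numbers, and leaving out each library in turn. Lists of equal length kept the highest scores, and ties were kept in order of chromosome and start. Both CM +Dox CHD7 lists had a median score of 3.81, shared with other CHD7 lists, and were cut near their median. Ties may therefore have decided which of their peaks stayed, while Control +Dox CHD7 replicate 1 was not cut. A common threshold of 1e-09 for RUNX1, the median score of the lists of the same antibody, and the comparisons of CHD7 at lost, gained and universally called RUNX1 sites were added after seeing the data. For the matched comparison and for gained sites at equal list length, the prediction was still written before that test's own result was seen. The scripts were run on simulated lists as a check of the code. Of 200 RUNX1 sites removed from the CM +Dox lists among 21664 sites, 100% were recovered, and of 200 CHD7 sites among 85223, 100%. These sites met the definition of a lost site by construction, so the recovery says nothing on sensitivity in the real lists. The random draw of the other sites gave 84 further lost RUNX1 sites and 90 further lost CHD7 sites. Of 200 random gene lists, 3% passed an unadjusted threshold of 0.05. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.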

Results

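ChIP-seq peaks of RUNX1 and CHD7 were compared in 416B mouse myeloid progenitor cells with and without induction of the leukaemia fusion protein Cbfb-Myh11 (CM). For each antibody there were 8 libraries, 2 in each of 4 conditions: cells with a control construct without or with doxycycline (Control -Dox, Control +Dox), and cells with the inducible fusion construct without or with doxycycline (CM -Dox, CM +Dox). Only CM +Dox cells were induced to make the fusion. The lists held 8140 to 16163 RUNX1 peaks covering 2.98 to 5.77 Mb, and 16323 to 37698 CHD7 peaks covering 7.21 to 16.7 Mb. Read depth behind the lists is unknown. Between replicates, 71.2% to 92.7% of the RUNX1 peaks of a library overlapped a peak of its partner, against 31.2% to 77.9% for CHD7. Library lists ended at different thresholds, and some results were computed again with a common p-value threshold of 1e-09 for RUNX1 lists only. Among them were RUNX1 peak numbers, retention, lost and gained sites, and gene-end shares. Co-occupancy and CHD7 at baseline and universally called sites were also among them. The CHD7 lists were left as deposited there, so CHD7 calls were not tested at 1e-09.

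The genes joined in the fusion were examined first, as a check of the labels. Cbfb encodes the non-DNA-binding partner of RUNX proteins, and Myh11 encodes smooth muscle myosin heavy chain. In all 4 CM +Dox libraries, with either antibody, peaks were called at the same 7 short intervals, 4 at Cbfb (chromosome 8, 105170674 to 105217989) and 3 in Myh11 (chromosome 16, 14194527 to 14292188). None of the 7 was called in any of the 8 control libraries. All 7 were called in both CM -Dox CHD7 libraries, and 4 of them in a CM -Dox RUNX1 library. One interval, at 105178439 to 105178860 in Cbfb, was called in both CM -Dox RUNX1 libraries. The 3 Myh11 intervals lay together between 14200562 and 14205770. Each of the 8 libraries labelled CM called at least 1 of the intervals. Exon positions were not used here.

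**Figure D1:**
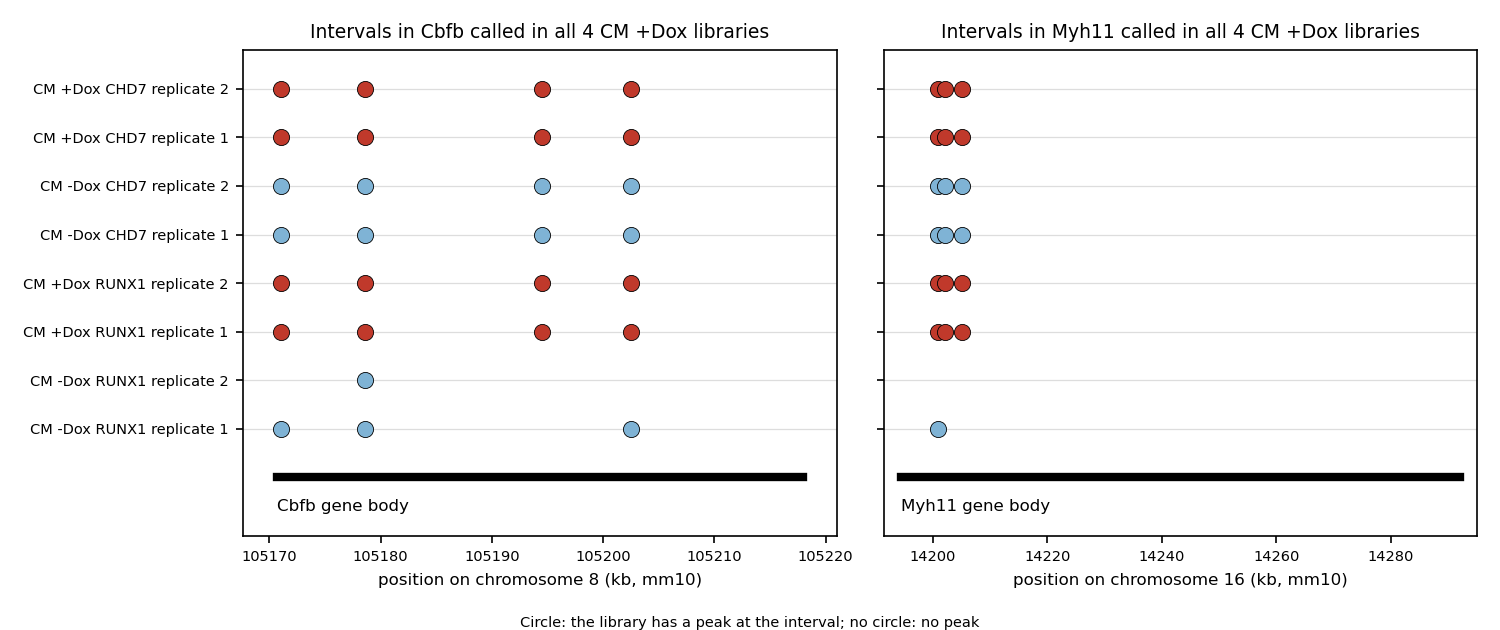
Position of the 7 intervals in Cbfb and Myh11 called in all 4 CM +Dox libraries (horizontal axis, kb on mm10) in the 8 libraries with the fusion construct (rows); a circle marks a peak of that library at the interval and the black bar is the gene body. Circles stand at all 7 places with both antibodies in CM +Dox, and none of the 8 control libraries, not drawn, called these intervals.

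RUNX1 peaks were fewer in the libraries with the induced fusion. CM +Dox libraries held 8925 ± 1110 RUNX1 peaks (SD, n = 2), against 13942 ± 1193 in the 6 libraries without CM. The ratio of geometric means was 0.640 (exact permutation test over 28 choices, p = 0.0357, the smallest possible; Benjamini-Hochberg adjusted p = 0.0612 over 12 tests). Of these 12 tests, which include all comparisons of CM +Dox with the rest given here with an adjusted p, only the gene-end share of RUNX1 against CHD7 passed 0.05 after adjustment. The ratio of RUNX1 peak numbers with to without doxycycline was 0.604 in cells with the fusion construct and 0.943 in control cells, a ratio of 0.641. As a difference of differences in peak number it was -5072.5 (exact permutation test over 36 splits, p = 0.167, with 0.0556 the smallest possible). Within replicate numbers, CM +Dox held 0.595 times the mean of the others for replicate 1 and 0.684 times for replicate 2. At the common threshold the ratio was 0.636. With peaks at or above the median RUNX1 score it was 0.566 and another choice of libraries gave as large a difference (exact p = 0.0714).

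Whether RUNX1 was called at its usual places was examined at 11460 baseline sites, those called in both Control -Dox libraries. CM +Dox libraries kept 50.9% and 59.5% of them, a mean of 55.2% ± 6.05 (SD, n = 2). Control +Dox libraries kept 89.8% ± 0.154 (n = 2) and CM -Dox libraries 88.5% ± 3.47 (n = 2). The difference of -34.0 percentage points was the largest of the 15 possible choices, and its exact p of 0.0667 is the smallest this design allows. With 8140 peaks in every list, which left 6529 baseline sites, the difference was -26.9 percentage points. Within replicate 1 it was -37.0 and within replicate 2 it was -31.0 percentage points.

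**Figure D2:**
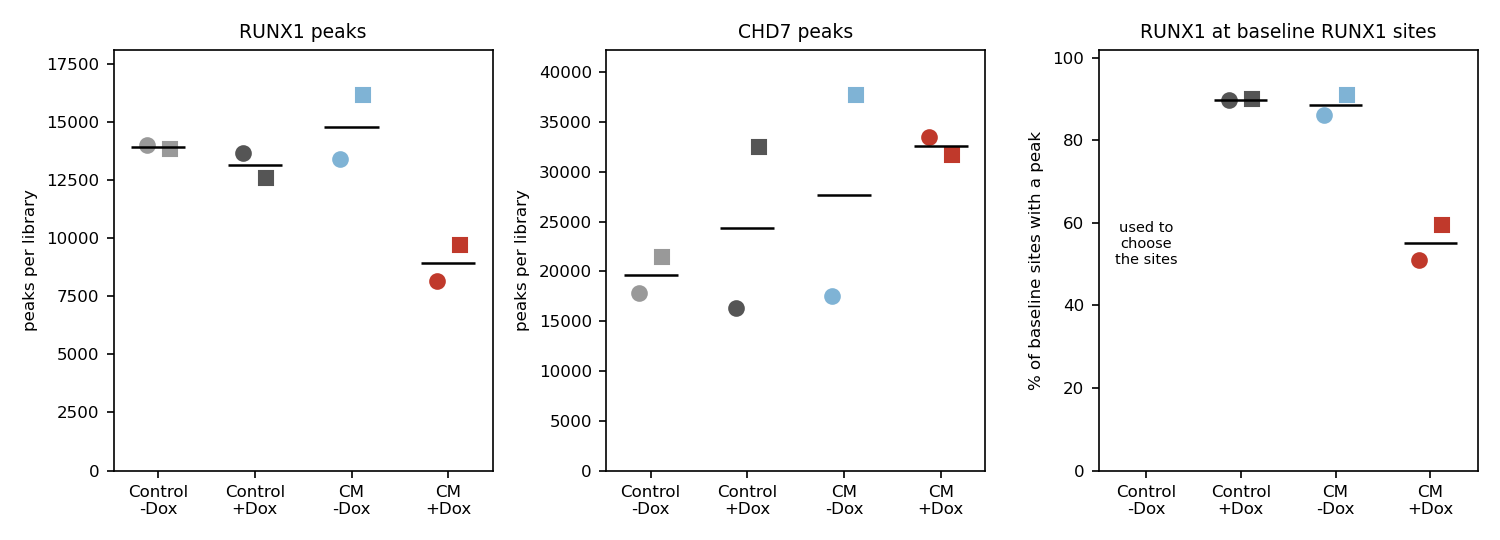
Peaks per library for RUNX1 (left) and CHD7 (middle), and the percentage of 11460 baseline RUNX1 sites with a RUNX1 peak (right), by condition; circles are replicate 1, squares replicate 2 and lines the mean of 2 libraries. Both CM +Dox RUNX1 libraries (8140 and 9710 peaks) lie below the other 6, while CHD7 peak numbers overlap between conditions.

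Site by site, 8531 RUNX1 sites were called in all 6 libraries without CM. Of these, 2384 (27.9%) were called in neither CM +Dox library, 1314 (15.4%) in 1 of them and 4833 (56.7%) in both. The next highest number of lost sites over the other 27 choices of libraries was 252. With 8140 peaks per list, 1151 sites were lost and the next highest number was 174, and with peaks at or above the median RUNX1 score 1398 were lost. Lost sites lay mostly away from gene ends: 34.1% (Wilson 95% interval 32.9% to 35.3%) of the 5928 distal sites were lost, against 14.0% (12.7% to 15.4%) of the 2603 sites within 1 kb of a gene end. Loss also varied with the rank of the site, from 35.0% of the 1707 lowest-ranked sites to 14.0% of the 1706 highest-ranked.

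Among the highest-ranked lost RUNX1 sites most lay outside genes. Among the 10 named, 2 lay within a gene. These were in Mctp1 (chromosome 13, 76421053 to 76421492) and in Pparg, a nuclear receptor of adipocyte and macrophage differentiation (chromosome 6, 115434019 to 115434463). The others were nearest to Actbl2 (chromosome 13, 111043611 to 111044129, 211 kb away), Map4k3 (43.9 kb), Nln (10.4 kb), Slc11a1, a metal transporter of macrophage phagosomes (1.43 kb), Mad2l1 (188 kb), the TGF-beta receptor gene Tgfbr2 (194 kb), Slc24a5 (53.0 kb) and Tmem132c (629 kb). Their mean percentile rank in the 6 libraries ran from 97.5 to 99.4. CHD7 was called at 7 of these 10 sites in all 6 CHD7 libraries without CM. At 5 of the 7 it was called in neither CM +Dox CHD7 library, namely those near Actbl2, Map4k3, Nln and Slc24a5 and in Pparg, and at the other two, in Mctp1 and near Tgfbr2, in 1.

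RUNX1 sites gained with CM were few in the lists as deposited. There were 181, fewer than the 658 that CM -Dox gave as the chosen pair, and 5 of the 28 choices gave as many. With 8140 peaks in every list the number was 902, against a next highest of 310. Sites that longer lists call only below that cut count as gained there. Besides 3 sites in Cbfb and Myh11, the 10 highest-ranked gained sites lay in Ubash3b, a phosphatase gene of T cell receptor signalling (chromosome 9, 41152859 to 41153219), Nr5a2 (chromosome 1, 136845337 to 136845713), Synj2, Fnip2, Slc24a4 and Ube2g1, and 54.9 kb from Clec14a. With peaks at or above the median RUNX1 score 6 of the 10 were still gained, those in Ubash3b, Nr5a2 and Fnip2 and the 3 in Cbfb and Myh11. Leaving out a CM +Dox library raised the number of gained sites to 642 without replicate 1 and 566 without replicate 2.

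Runx1 itself, with the highest RUNX1 rank in the list of haematopoietic transcription factors, held 9 to 11 RUNX1 peaks per library without CM (chromosome 16, 92601466 to 92826074) and 6 and 7 in CM +Dox. Counting 5 kb on either side, 3 of its 9 sites called in all 6 libraries were lost. Chd7 (chromosome 4, 8690402 to 8868449) held 2 to 4 RUNX1 peaks per library without CM, and 0 and 2 in CM +Dox.

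Across the gene lists, the genes with a reproducible RUNX1 site in CM -Dox and in CM +Dox numbered 20 and 15 of 24 haematopoietic stem and progenitor transcription factors. The 5 without one in CM +Dox were Gata2, Tal1, Fli1, Gfi1b and Ikzf1, and none was new. Cbfb, with the intervals described above, is counted in both numbers. Of 25 myeloid differentiation genes the numbers were 11 and 9, with Cebpa, Cebpe and Itgam without a site shared by both CM +Dox replicates and Csf2rb newly with one. Of 20 megakaryocyte and mast cell genes they were 10 and 7, without Gp9, Kit and Cpa3. Ribosomal protein genes went from 19 to 13 of 27, cell cycle genes from 18 to 14 of 20 (without Cdk1, Cdkn1a, Myc and Mcm5), signalling genes from 13 to 11 of 20 and erythroid genes from 4 to 3 of 12. Chromatin remodellers stood at 11 of 15 in both, with Chd7 and Chd8 bound in CM -Dox alone and 2 others in CM +Dox alone. Lymphoid genes stood at 1 and 0 of 16, neural crest genes at 1 (Sema3a) and 2 (Sox4 and Tfap2a) of 16 and liver genes at 0 of 12 in both. Among all 21883 genes, 7220 were bound in CM -Dox and 5367 in CM +Dox (2331 no longer bound, 478 newly bound), against 6939 in Control -Dox and 6373 in Control +Dox (976 and 410). No list passed the test of its share of lost sites against that of all other sites (Fisher's exact test per list, 11 tests, lowest adjusted p = 0.549). Lost were 9 of 21 sites of the megakaryocyte and mast cell list, 8 of 19 of the chromatin remodeller list and 1 of 17 of the ribosomal protein list.

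CHD7 peak numbers did not separate CM +Dox from the rest. CM +Dox libraries held 32575 ± 1254 CHD7 peaks (SD, n = 2), against 23894 ± 8983 in the other 6, a ratio of geometric means of 1.44 (exact permutation test, p = 0.321). The ratio of CM +Dox to the mean of the others was 1.94 for replicate 1 and 1.04 for replicate 2. The ratio with to without doxycycline was 1.27 in cells with the fusion construct and 1.17 in control cells.

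At RUNX1 sites, CHD7 was found less often where RUNX1 was lost. At the 2384 lost RUNX1 sites, CHD7 was called at 25.0% ± 5.31 (SD, n = 2) in CM +Dox and 43.1% ± 7.90 (n = 6) without CM, a difference of -18.1 percentage points (exact permutation test, p = 0.0357, the smallest possible; adjusted p = 0.0612). At the 4833 RUNX1 sites called in all 8 libraries it was called at 60.6% ± 10.5 (n = 2) and 63.5% ± 7.86 (n = 6), a difference of -2.96 percentage points (exact p = 0.643). The log2 odds ratio of CHD7 at lost against universally called sites was -2.24 ± 0.23 (n = 2) in CM +Dox and -1.23 ± 0.11 (n = 6) without CM (exact permutation test, p = 0.0357; adjusted p = 0.0612). At the 181 RUNX1 sites gained with CM, CHD7 was called at 48.6% ± 5.47 (n = 2) in CM +Dox and 24.3% ± 4.78 (n = 6) without CM (exact permutation test, p = 0.0357; adjusted p = 0.0612). With 16323 CHD7 and 8140 RUNX1 peaks per list, the difference at 902 gained sites was 8.09 percentage points (exact permutation test, p = 0.143). These comparisons were added after the peak lists had been examined.

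At lost sites the difference was -15.1 percentage points within replicate 1 and -21.1 within replicate 2. Away from gene ends, CHD7 was called at 41.5% of 2019 lost sites on average without CM and 21.1% in CM +Dox, against 52.0% and 46.4% of 365 lost sites within 1 kb of a gene end. With peaks at or above the pooled median score, the difference at lost sites was -5.88 percentage points (exact permutation test, p = 0.357), with those at or above the median score of each antibody, at 1398 lost sites, -17.3 and with an overlap of 0.5 of the shorter interval -18.2 (exact p = 0.0714 for both). Without Control -Dox replicate 2 it was -17.0 and without Control +Dox replicate 2 it was -17.5 (exact p = 0.0952 for both). With 16323 CHD7 and 8140 RUNX1 peaks per list, CHD7 at the 3066 RUNX1 sites then called in all 8 libraries differed by -14.4 percentage points (exact permutation test, p = 0.0357). The effect of tied CHD7 scores at the cut was not tested.

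**Figure D3:**
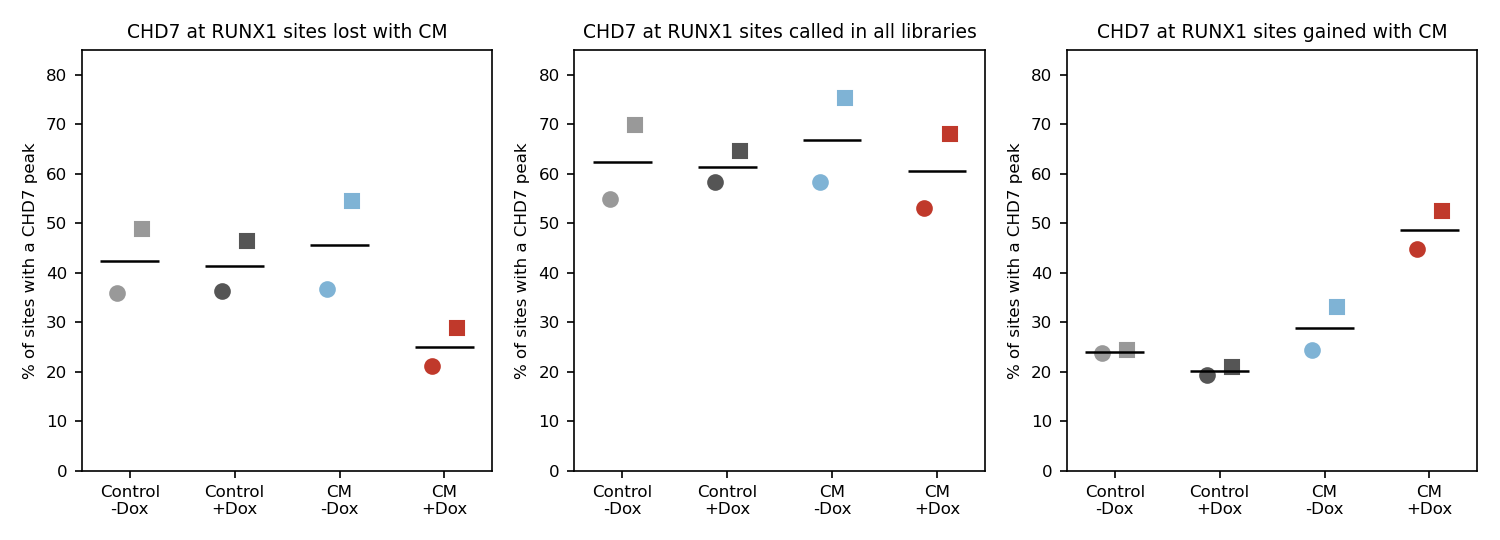
Percentage of RUNX1 sites with a CHD7 peak in each CHD7 library (vertical axis) by condition, at 2384 RUNX1 sites lost with CM (left), 4833 called in all 8 RUNX1 libraries (middle) and 181 gained with CM (right); circles are replicate 1, squares replicate 2 and lines the mean of 2 libraries. CM +Dox lies below the other 6 libraries at lost sites (21.2% and 28.7%) and above them at gained sites (44.8% and 52.5%), and overlaps them at universally called sites.

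Over all 11460 baseline RUNX1 sites, CHD7 was called at 45.4% ± 8.76 (n = 2) in CM +Dox and 52.5% ± 7.47 (n = 6) without CM, a difference of -7.06 percentage points (exact permutation test, p = 0.286). It was -6.99 within replicate 1 and -7.12 within replicate 2. With 16323 CHD7 and 8140 RUNX1 peaks per list, which left 6529 baseline sites, the difference was -16.3 percentage points (exact permutation test, p = 0.0357). CHD7 peaks with tied scores at the cut were kept by position, and the effect of this was not tested. With the pooled median score the difference turned to 0.26. Relative to CHD7 sites away from RUNX1, the log2 odds ratio of CHD7 at RUNX1 sites was 1.58 ± 0.79 (n = 2) in CM +Dox and 3.18 ± 0.61 (n = 6) without CM, a difference of -1.60 (exact permutation test, p = 0.0357; adjusted p = 0.0612). This ratio also went with list length. It was 1.02 and 2.13 in CM +Dox, whose lists are long. The long lists without CM, Control +Dox replicate 2 and CM -Dox replicate 2, had 2.24 and 2.72, and the shorter lists 3.18 to 3.92. At equal list length the difference was -1.49 (exact permutation test, p = 0.0357). Of 9448 CHD7 sites on baseline RUNX1 sites, 57.7% ± 9.04 (n = 2) were called in CM +Dox and 65.1% ± 8.73 (n = 6) without CM. Of 69332 CHD7 sites away from RUNX1, 31.5% ± 3.71 (n = 2) were called in CM +Dox and 19.1% ± 10.7 (n = 6) without CM, where libraries ran from 10.3% to 34.5%. Away from RUNX1, CM +Dox stood at 34.1% against a mean of 11.5% within replicate 1, and at 28.9% against 26.6% within replicate 2. The log2 odds ratio difference was -2.38 within replicate 1 and -0.83 within replicate 2. Without Control -Dox RUNX1 replicate 2 it was -1.49 (exact permutation test, p = 0.0714).

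CHD7 sites lost and gained with CM were set against the RUNX1 sites. Of the 211 CHD7 sites lost with CM, 154 (73.0%, Wilson 95% interval 66.6% to 78.5%) overlapped a RUNX1 site called in all 6 libraries without CM, against 46.8% (45.4% to 48.2%) of 4852 CHD7 sites called in all 8 libraries. Of the 1181 gained CHD7 sites, 20 (1.69%, 1.10% to 2.60%) did, against 8.68% (8.49% to 8.87%) of all 85223 CHD7 sites. Gained sites were by definition called in none of the 6 libraries without CM. This keeps their share at RUNX1 sites of those conditions low, so it cannot be read against that of lost sites. At gained RUNX1 sites lay 1.19% (0.71% to 1.98%) of gained CHD7 sites, against 0.135% of all. At lost RUNX1 sites lay 29.9% of lost CHD7 sites, against 6.12% of those called in all 8 libraries. At RUNX1 sites in all 8 libraries the shares were 31.8% and 34.7%. The counts themselves did not stand apart from other groupings of the libraries. Control -Dox replicate 1 with Control +Dox replicate 1 gave 259 lost sites, and CM -Dox replicate 2 with CM +Dox replicate 2 gave 1640 gained sites. With 16323 peaks per list the numbers were 311 lost and 467 gained, against 231 and 454 for the next highest choices, and with the pooled median score 39 and 597. Gained CHD7 sites numbered 8624 without CM +Dox replicate 1 and 14162 without replicate 2, and lost ones 355 and 793.

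The highest-ranked lost CHD7 site was in B4galnt2 (chromosome 11, 95875744 to 95876100), a glycosyltransferase gene, and no RUNX1 library called it. The other 9 were at RUNX1 sites called in all 6 libraries without CM. They lay in Mmp9, a matrix metalloproteinase gene of neutrophils and macrophages (chromosome 2, 164942706 to 164943447), and Stpg2, and nearest to Olfm3 (13.9 kb), 4930503B20Rik (0.850 kb), Glrx (22.5 kb), Ptpn1 (90.2 kb), the Wiskott-Aldrich gene Was (11.9 kb), Eea1 (159 kb) and Gja1 (462 kb). With the pooled median score 5 of the 10 were still lost, those in B4galnt2 and Mmp9 and near Olfm3, Glrx and Ptpn1. RUNX1 was called in neither CM +Dox library at 3 of the 9 (Glrx, Was and Eea1) and in both at 5. The 10 highest-ranked gained CHD7 sites lay in Syne1, Atg5, an autophagy gene, Lpp, Myh10 and Slc45a4, and nearest to Epgn (chromosome 5, 91043573 to 91043880, 8.51 kb), Rap2b (72.9 kb), Tmem243 (13.7 kb), the lipoprotein lipase gene Lpl (19.6 kb) and Tnfsf4 (44.1 kb). At 7 of these 10, no RUNX1 library called a peak.

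RUNX1 and CHD7 shared sites far more often than shifted peaks in every condition. Of the reproducible RUNX1 sites, 40.9% (Wilson 95% interval 40.0% to 41.8%, 4706 of 11508) carried reproducible CHD7 in Control -Dox, 40.0% (39.1% to 40.9%) in Control +Dox, 44.8% (43.9% to 45.7%) in CM -Dox and 45.5% (44.3% to 46.6%) in CM +Dox. The observed shares were 28.7, 29.5, 23.7 and 23.2 times those of shifted peaks, which were 1.43%, 1.36% and 1.89% in the first 3 conditions. With shifts of 100 to 1000 kb the mean was 50.6-fold, against 26.3. Read from CHD7, 44.9% of 10331 sites carried RUNX1 in Control -Dox, 42.6% of 9736 in Control +Dox, 41.2% of 13147 in CM -Dox and 21.9% of 14145 in CM +Dox. Shifted peaks gave 1.78% in CM -Dox and 0.968% in CM +Dox, so these shares were 28.7, 29.3, 23.1 and 22.7 times those of shifted peaks. Each condition has a single value here, so these shares have no replicate error.

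Called in all 16 libraries were 1530 RUNX1 sites, 31.7% of those in all 8 RUNX1 libraries. By rank, the first of them lay 145 kb from Reep3 (chromosome 10, 66864153 to 66864966), with a mean percentile rank of 98.9. The next lay 0.099 kb from Rgs18, a regulator of G protein signalling in megakaryocytes and platelets (chromosome 1, 144775251 to 144775802). Others lay in Cc2d2b, Sema4d, Rnf216, Sptbn1 and the adiponectin receptor gene Adipor2, and nearest to Rgs1 (81.3 kb), Klra17 (7.02 kb) and Rbm46 (42.6 kb).

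RUNX1 peaks lay near gene ends more often than CHD7 peaks. The share within 1 kb of a gene end was 27.2% to 35.8% in RUNX1 libraries without CM and 38.6% and 45.5% in CM +Dox, against 15.6% to 25.6% in CHD7 libraries. Shifted peaks gave 5.54% to 7.90%. The difference between antibodies was 12.8 percentage points (exact permutation test over 12870 splits, p = 0.000155, the smallest possible; adjusted p = 0.00187). It was 6.31 percentage points with equal numbers of peaks within each antibody (exact permutation test, p = 0.0684), 5.52 with the median score per antibody (exact p = 0.199) and 2.44 with the pooled median score (exact p = 0.427). Among RUNX1 libraries the CM +Dox share was 42.0% ± 4.90 (n = 2), against 31.0% ± 3.77 (n = 6) in the rest (exact permutation test, p = 0.0357; adjusted p = 0.0612). It was higher by 11.5 percentage points within replicate 1 and by 10.7 within replicate 2. For CHD7 the shares were 17.4% ± 2.55 (n = 2) and 22.1% ± 3.83 (n = 6; exact permutation test, p = 0.321).

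In Control -Dox cells, RUNX1 sites marked several gene groups more often than random genes of the same length. Genes given below as leading or ranked highest were ordered by mean RUNX1 rank over all 8 libraries, CM +Dox included, not in Control -Dox alone. RUNX1 was at 20 of 24 haematopoietic stem and progenitor transcription factors (83.3%, 37.8% in random lists, adjusted permutation p = 0.0011 over 22 tests), led by Runx1, Zfpm1, Nfe2 and Lyl1. It was at 21 of 27 ribosomal protein genes (77.8% against 23.0%, adjusted permutation p = 0.0011), led by Rps9, Rpl18, Rpl35 and Rps19, and at 17 of 20 cell cycle genes (31.6% in random lists, adjusted permutation p = 0.0011), led by Ccnd3, E2f2, Cdk6 and Cdk2. Chromatin remodellers followed with 12 of 15 (80.0% against 43.8%, adjusted permutation p = 0.0466), led by Arid1b, Chd2, Chd4 and Ep400. That call was not made with 50 kb windows (adjusted permutation p = 0.0851) or gene ends (0.286), nor in Control +Dox (0.0550) or CM -Dox (0.114), but was made in CM +Dox, 11 of 15 (0.0095), there also with 50 kb windows (0.0161) and gene ends (0.0275). The other lists did not pass with 5 kb windows in Control -Dox. Signalling genes had 13 of 20 (adjusted permutation p = 0.0503; Il6ra, Dusp6, Flt3 and Cd34 ranked highest), megakaryocyte and mast cell genes 10 of 20 (0.213; Selp, Plek, Itgb3 and Itga2b), and myeloid differentiation genes 9 of 25 (0.380; Prtn3, Fcgr3, Cebpd and Egr1). Erythroid genes had 4 of 12 (0.835; Klf1, Epor, Hbb-bt and Tfrc), lymphoid genes 3 of 16 (0.380), neural crest genes 1 of 16 (0.104) and liver genes 0 of 12 (0.0503). In other conditions RUNX1 passed at signalling genes in Control +Dox, 13 of 20 (adjusted permutation p = 0.0220), and CM +Dox, 11 of 20 (0.0425), and was below random lists at liver genes in CM -Dox, 0 of 12 (0.0418), and lymphoid genes in CM +Dox, 0 of 16 (0.0425). With 50 kb windows, of these calls only that of signalling genes in Control +Dox was made (adjusted permutation p = 0.0026; the others 0.0844, 0.321 and 0.908), and with gene ends none (0.216 to 0.796). With 50 kb windows in Control -Dox RUNX1 also passed at signalling genes, 20 of 20 (adjusted permutation p = 0.0022), myeloid differentiation genes, 21 of 25 (0.0069), and erythroid genes, 10 of 12 (0.0386), and was below random lists at neural crest genes, 3 of 16 (0.0143). These p-values come from permutation of gene lists, not from libraries.

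CHD7 in the same cells was at 17 of 27 ribosomal protein genes (63.0%, 17.3% in random lists, adjusted permutation p = 0.0011), the only list to pass. Haematopoietic transcription factors had 13 of 24 and signalling genes 11 of 20 (both adjusted permutation p = 0.0871), and cell cycle genes 9 of 20 (0.170). Chromatin remodellers had 9 of 15 (0.213), megakaryocyte and mast cell genes 9 of 20 (0.198) and myeloid differentiation genes 6 of 25 (0.815). Erythroid genes had 3 of 12 (1.0), lymphoid genes 3 of 16 (0.680), neural crest genes 2 of 16 (0.543) and liver genes 0 of 12 (0.0871). CHD7 also passed at haematopoietic transcription factors with the sites of each other condition: 14 of 24 in Control +Dox (adjusted permutation p = 0.0251), 18 of 24 in CM -Dox (0.0018) and 17 of 24 in CM +Dox (0.0066). It passed at cell cycle genes in Control +Dox, 12 of 20 (0.0079), and CM +Dox, 12 of 20 (0.0163). With gene ends none of these calls was made (adjusted permutation p from 0.179 to 0.843), and with 50 kb windows those of cell cycle genes were not (0.325 and 0.463). Differences between conditions were not tested. From CM -Dox to CM +Dox, Tal1, Spi1 and Nfe2 among the transcription factors, and Elane, Lyz2 and Cd68 among the myeloid genes, had a CHD7 site shared by both replicates in CM -Dox and none in CM +Dox. For Runx3, Lmo2, Csf1r and Csf2rb it was the reverse. Turnover of this size also occurred without the fusion: of all genes, 1104 were no longer and 1439 newly bound by CHD7 from CM -Dox to CM +Dox, against 1256 and 995 from Control -Dox to Control +Dox.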

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

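The test below was chosen after its result was seen. Cbfb and Myh11, the genes whose cDNA was used to build the fusion construct, carried peaks in the fusion libraries that control libraries lacked: 4 intervals in Cbfb and 3 in Myh11 were called in all 4 CM +Dox libraries and in none of the 8 control libraries. RUNX1 and CHD7 antibodies gave the same places: of the 7 intervals called with RUNX1 in CM +Dox, 100% were also called with CHD7. Of all reproducible RUNX1 sites in CM +Dox, 45.5% carried CHD7. A candidate explanation is that reads from the integrated construct were aligned to the endogenous genes. The intervals were chosen as those called in all 4 CM +Dox libraries, so only their absence from control libraries (7 of 7) and their recurrence in uninduced libraries (7 of 7) could have come out otherwise, as could the sharing of RUNX1-called intervals with CHD7. With RUNX1 the recurrence was incomplete, since 4 of the 7 were called in an uninduced RUNX1 library. The construct is carried with and without doxycycline, so its presence alone does not account for this dependence on induction. Unknown read depth was not separated from it. What stays open is binding of both proteins at the endogenous genes, which needs exon positions and input reads not used here, and no biological explanation was tested. If construct reads are the source, 3 of the 181 RUNX1 sites counted as gained with CM would not be binding events, which leaves 178. Cbfb would then also rest on construct reads where it counts as bound by RUNX1 in CM +Dox, among the 15 of 24 haematopoietic transcription factors.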

How the results depend on the processing

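The common RUNX1 threshold, the median score per antibody, the results on CHD7 at lost, gained and universally called RUNX1 sites, and the count of gained RUNX1 sites without Cbfb and Myh11 (178) were added after seeing the data; the other alternatives were fixed before the data were examined. Leaving aside left-out libraries, 90 comparisons of an alternative with its reported result kept direction and side of the threshold or stayed within the spread between replicates, 19 moved beyond it, 7 lost and 2 gained a call, and 3 reversed. Where an alternative's test cannot reach 0.05, its value was compared with the spread alone. The 90 include results fixed in advance, such as values that the replicate block cannot change and RUNX1-only results at the pooled median score. The loss of RUNX1 peaks and of baseline sites kept its direction in every alternative run, as did CHD7 preference for RUNX1 sites. Equal list length has no value for peak numbers, and the pooled median score (4.79) removes no RUNX1 peak, so it says nothing on RUNX1-only results. RUNX motif alternatives were not run without a genome. The cause of each change below was not tested unless stated.

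With the pooled median score, CHD7 sites numbered 39 lost and 597 gained, CHD7 at baseline sites differed by 0.26, at lost sites by -5.88 and at universally called sites by 2.17 percentage points, the gene-end difference between antibodies was 2.44 points, and co-occupancy was 31.8-fold (26.3 as reported, mean of 4 conditions). Equal list length gave 1151 lost and 902 gained RUNX1 sites, 467 gained CHD7 sites, retention of -26.9, CHD7 at baseline sites of -16.3 and at universally called sites of -14.4 percentage points, a gene-end difference of 6.31 and co-occupancy of 30.4-fold. With the median score per antibody the RUNX1 peak ratio was 0.566, the doxycycline ratio of constructs 0.516 for RUNX1 and 0.978 for CHD7, RUNX1 lost sites 1398, CHD7 lost and gained sites 107 and 763, retention -44.7, CHD7 at lost sites -17.3, the gene-end difference 5.52 and co-occupancy 32.0-fold. An overlap of 0.5 gave CHD7 at lost sites of -18.2 (exact p = 0.0714) and co-occupancy of 37.2-fold. Shifts of 100 to 1000 kb gave 50.6-fold and the union of replicates 17.7-fold. CHD7 marked 4 lists more often than random lists with 50 kb windows and 3 with CM +Dox sites, against 1; with 50 kb windows neural crest and liver genes were below random lists (adjusted permutation p = 0.0356 for both). For RUNX1 the numbers of lists were 6, 5 and 4, and 3 with gene ends.

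Over left-out libraries the ranges were -38.3 to -29.7 percentage points for retention, -2.23 to -1.10 for CHD7 preference, -21.9 to -14.3 for CHD7 at lost sites, -10.4 to 4.47 at universally called sites (above 0 without CM +Dox CHD7 replicate 1), -13.2 to -0.86 at baseline sites and -1.17 to -0.73 for the log2 odds ratio. They were 23.8 to 26.6 for co-occupancy, 0.735 to 1.58 for the CHD7 doxycycline ratio (below 1 without Control -Dox replicate 2, Control +Dox replicate 1 or CM -Dox replicate 1), 190 to 642 gained RUNX1 sites, 238 to 793 lost CHD7 sites and 1264 to 14162 gained CHD7 sites. Gained CHD7 sites numbered 1931 without CM -Dox replicate 2, 8624 without CM +Dox replicate 1 and 14162 without CM +Dox replicate 2, and lost ones 336 without CM -Dox replicate 1. CHD7 preference lost its call without Control -Dox RUNX1 replicate 2 (-1.49, exact p = 0.0714). CHD7 at lost sites lost its call without Control -Dox CHD7 replicate 2 (-17.0) or Control +Dox CHD7 replicate 2 (-17.5; exact p = 0.0952 for both).

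The replicate numbers were not taken to pair the libraries: correlations of same-numbered deviations ran from 0.02 to 0.22 for RUNX1 and -0.09 to 0.07 for CHD7. With a replicate block, values such as the RUNX1 peak ratio of 0.640 are unchanged by construction, and its 16 choices cannot give an exact p below 0.0625. CHD7 at baseline, lost and universally called RUNX1 sites was nevertheless higher in replicate 2 than in replicate 1 in all 4 conditions. The RUNX1 gene-end share was higher in replicate 1 in all 4. The exact p-values of 0.0357 treat the 8 libraries of an antibody as exchangeable, and within replicate numbers they could not fall below 0.0625. With the block, the difference of -7.06 in CHD7 at baseline sites had that smallest exact p of 0.0625. Unknown read depth limits every peak number.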

Other observations

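The tests of equal list length, of chance choices of libraries and of odds ratios of CHD7 at lost against universally called sites were chosen after the results were seen; the predictions for the highest-ranked sites, matched CHD7 calls and gained sites at equal list length were written before those results were seen.

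CHD7 at universally called RUNX1 sites away from gene ends stood at 68.9% on average without CM and 62.6% in CM +Dox (2921 sites), and at those within 1 kb of a gene end at 55.3% and 57.5% (1912 sites). Across 5 equal groups of RUNX1 rank, CHD7 without CM was called on average at 57.3% of sites in the lowest, 48.2%, 50.6% and 57.2% in the middle ones, and 72.2% in the highest. The share of sites within 1 kb of a gene end was lower in each higher group, from 50.1% in the lowest group to 12.2% in the highest. Among the named genes, Plek, a platelet kinase substrate gene, and Selp, the P-selectin gene, held RUNX1 and CHD7 in all 16 libraries with mean RUNX1 ranks of 99.2 and 99.6. Cd79a and Rag2, lymphoid genes, had CHD7 in the gene or within 5 kb in all 8 libraries, with mean ranks of 99.99 and 97.8. Their mean RUNX1 ranks were 35.2 and 7.05, counting 0 where a library had no peak. At Rag2, RUNX1 was called in 2 of the 6 libraries without CM and in neither CM +Dox library. The difference of doxycycline effects between constructs cannot go below an exact p of 0.0556 over 36 splits.

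Loss of RUNX1 sites with CM was set against technical explanations. Shorter lists alone would lower the number of lost sites to that of other choices of libraries, but with 8140 peaks in every list 1151 sites were lost, against at most 174 for the other choices. At that length 902 sites were also gained, against at most 310, while the lists as deposited gave 181. Sites that longer lists call only below the cut count as gained there. Lists of equal length therefore show a shift in which sites rank highest, and cannot show a net loss. A weaker immunoprecipitation that drops the weakest sites first would leave the highest-ranked group of 5 nearly untouched, but 13.95% of it was lost (238 of 1706 sites, 95% interval 12.4% to 15.7%), although loss was heavier at 35.0% in the lowest. Only 1 of the 28 choices of 2 libraries, the real one, gave as many lost sites as the 2384 observed. The highest other gave 252. That share is the smallest that 28 choices allow, and it was taken after the count was seen and without adjustment. A chance choice of libraries is therefore made less likely but not excluded. The remaining hypothesis, that the fusion protein may move RUNX1 from part of its sites, was not tested against RUNX1 protein level, antibody access in the presence of the fusion, or differences in background library, and 1 RUNX1 list carried a doxycycline tag against its label.

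CHD7 was called less often at lost RUNX1 sites in CM +Dox, and weaker CHD7 sites could drop out first. When lost and universally called sites were matched on the number of CHD7 libraries without CM that call them, the CM +Dox differences were -15.84 and -23.34 percentage points, and the 6 libraries without CM, each matched on the other 5, ran from -6.59 to 0.25. A lower CHD7 yield that cut the odds of a call equally at all RUNX1 sites would leave the odds ratio between the site classes in its usual range. The CM +Dox log2 odds ratios were -2.07 and -2.40, below the -1.35 to -1.08 of the others. This argues only against such an equal drop as the whole cause. A drop that takes more calls where CHD7 is weaker could also move the odds ratio, and lower yield and weaker sites were not tested together. At equal list length CHD7 was lower at universally called sites (-14.4 percentage points) and at lost sites (-24.3), and the log2 odds ratio differed by -1.32. Tied CHD7 scores at the cut limit these values. If CHD7 followed RUNX1 to gained sites too, both CM +Dox libraries were predicted to exceed all libraries without CM, also at equal list length. There CM +Dox replicate 1 had CHD7 at 31.82% of 902 gained sites, within the range of libraries without CM, which reached 32.93%. Replicate 2 had 41.13%, above that range. The outcome set beforehand against the prediction, a CM +Dox library within the range, was therefore met. It rests on 1 library, and which sites count as gained depends on the cut, so the question is not settled. A hypothesis left by these tests is that CHD7 may leave sites together with RUNX1; they do not show which goes first, and at a pooled median score the CHD7 difference at lost sites was -5.88 percentage points.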
